A study of Mus musculus with 9 samples.

How the data were processed

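The RNA-seq data are 9 libraries of 3 separate experiments in mouse brown fat and in cultured brown adipocytes, 4 of BAT, 2 of 4-OHT and ETOH cells and 3 of siRNA cells. Per the labels, libraries were made with NEBNext Ultra II chemistry and read on an Illumina NovaSeq. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10a, featureCounts 2.0.3, DESeq2 1.36.0 and the mouse build GRCm38, with no role or order for the tools. The annotation release, the strand setting of the counting and the handling of reads that map to several places were not stated.

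The deposited tables of BAT and siRNA hold a signal per gene and library, which is the read count times 1 factor per library, scaled by the authors. The deposited 4-OHT table holds a raw count per gene, the same count scaled, and an FPKM, scaled for gene length and depth, by the authors. Each deposited table also holds a log2 fold change, a p-value with its adjusted form, and a gene length, per the file headers. The FPKM, gene length, group means and fold changes of the authors were not used here, and the p-values of the authors serve only for counts named as theirs. Whole reads were recovered from the signal by dividing each column by its step, and 100% of values lay within 0.05 reads of a whole number. The siNC library gave the same recovered reads in all 19381 genes present in both siRNA tables, so the tables were joined through it with a link factor of 1.0024. Genes absent from 1 siRNA table had at most 1 siNC read and were counted as 0 there. The tables hold 29386 gene identifiers, of which 29373 are in the reference annotation, 97.5% of these with the same start and end, and 24 symbols that had been turned into dates were restored from the identifier.

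The design written before the data were examined assumed raw counts and the edgeR quasi-likelihood test. Because the deposited unit is a scaled signal, the test was changed to limma on log2(normalised count + 1), with lmFit and eBayes with a trend, and edgeR on recovered reads became an added alternative. Fold changes on this scale understate changes of genes with few reads. Genes entered with at least 10 normalised counts in at least 2 BAT libraries or at least 1 siRNA library, and were called at a Benjamini-Hochberg false discovery rate below 0.05. The p-values measure only the spread between these libraries. In the siRNA experiment the lone siNC library is assumed to vary like the siSetdb1 libraries, with 1 residual degree of freedom. The 4-OHT experiment has 1 library per group, so log2 ratios of TMM-scaled CPM (library-scaled counts) with a prior count of 2 were described, for genes with at least 50 counts in 1 library.

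Gene lists numbered 29 and were fixed with the design. Lists with at least 5 measured members were tested in BAT (28 lists) and siRNA (25) with limma camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The estimated correlation rests on few residual degrees of freedom, 1 in siRNA, so hardly any list could pass with it. A call lost in that setting therefore says little of the list concerned. Counts of called members are given over all genes and adjusted over the list alone. In 4-OHT a list median was placed among 10000 random lists of its size matched on 20 bins of expression. Genes called in BAT were followed into the cells the same way. The random lists draw genes without regard to shared regulation, so a percentile is a description and not a test. The genes named by rule were Setdb1, a fixed set of brown fat and adipocyte genes, the 10 protein-coding genes with the largest fitted change in each direction in BAT among called genes with an average log2 CPM of at least 1 and all libraries on 1 side, the called protein-coding genes of the siRNA experiment and the next by the smaller change of its libraries, the 10 protein-coding genes with the largest ratios each way in 4-OHT, and at most 10 genes shared by all experiments at 1.5-fold. Examples of a list were taken by rule from its 4 members with the smallest p or, in 4-OHT, the highest mean CPM. Other genes were chosen after their values were seen.

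The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With the BAT design, 33% of the 2-fold and 97% of the 4-fold changes were called among 14338 genes, with 2 false calls. With the siRNA design, 89% and 100% were called among 15008 genes, with 8 false calls. All simulated genes of an experiment shared 1 dispersion, and the changed genes were drawn only from those above a minimum mean count. Real genes vary unequally, so these shares and false calls do not carry over to the measured genes. Of 200 simulated lists without a shift, 0 passed the list test. Genes in these lists were simulated independently of one another, so this does not measure false calls for lists of correlated genes. The biological coefficient of variation was 0.192 in BAT and 0.095 in siRNA (edgeR). A ratio against 1 to 3 control reads carries a 95% counting interval, and a gene with no control read is compared with a floor of 3 reads over the group. Intervals and floors cover counting error only.

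Alternatives mostly changed 1 choice at a time. The choices were tool, scaling, filter, pseudocount, threshold, variance prior, libraries in the fit, each library left out and the replicate number as a block. The edgeR fits also used recovered reads and a filter of their own, and edgeR with the replicate block changed both tool and block. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here, so the deleted part of Setdb1, splicing and transposable elements were not measured.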

Results

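RNA was sequenced from mouse brown adipose tissue (BAT) and from primary brown adipocytes in which Setdb1 was deleted or knocked down. Setdb1 encodes a methyltransferase for lysine 9 of histone H3, a mark of silenced chromatin. The first experiment held 2 control mice without Adipoq-Cre and 2 Setdb1 AKO mice, in which Adipoq-Cre, a recombinase expressed in adipocytes, acts on floxed Setdb1. The second held floxed cells with a tamoxifen-inducible Cre at Rosa26, 1 library treated with 4-hydroxytamoxifen (4-OHT) and 1 with its ethanol vehicle (ETOH). The third held 1 library of cells given a control siRNA (siNC) and 2 libraries given siRNA against Setdb1 (siSetdb1). Total reads on genes were 16940622 and 15979479 in the control BAT libraries, 16576169 and 16057065 in the Setdb1 AKO libraries, 29911734 in ETOH and 30176359 in 4-OHT. They were 18468152 in siNC and 17721078 and 17593799 in the siSetdb1 libraries 1 and 2. The BAT labels carry the prefix TN_CE, which they do not explain. The ages, sex and housing of the mice were not given otherwise, and neither was whether the siSetdb1 libraries used the same siRNA. Each BAT library held from 4373 to 5626 reads of Xist, the RNA of X inactivation. All had 0 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, the pattern of female tissue. The experiments share no library, so each was compared with its own control. No BAT library came from mice with Adipoq-Cre and intact Setdb1. Effects of the Cre in BAT therefore cannot be told apart from deletion of Setdb1.

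The targeted gene was lower in every library with Setdb1 deleted or knocked down than in its control. Setdb1 (ENSMUSG00000015697, GRCm38 chromosome 3, 95323525 to 95357202) fell from 464 ± 12.6 normalised counts in control BAT to 174 ± 24.4 in Setdb1 AKO BAT (mean ± SD, n = 2 mice each), a log2 fold change of -1.42 (SE 0.19; limma, adjusted p = 0.0216). In the siRNA experiment it read 783.5 normalised counts in siNC and 370.9 and 399.2 in the siSetdb1 libraries, a log2 fold change of -1.02 (SE 0.15; limma, adjusted p = 0.0526). In the 4-OHT experiment it read 1070 counts in ETOH and 620 in 4-OHT, a log2 ratio of -0.73, with no replicates. These values sum reads over the whole gene, so they do not measure the floxed part alone. The call in BAT was lost without control 1 (limma, adjusted p = 0.225), without control 2 (0.230) and with no filter on low values (0.206), while the adjusted p of the siRNA value ranged from 4.68e-07 to 1 over the alternatives.

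**Figure D1:**
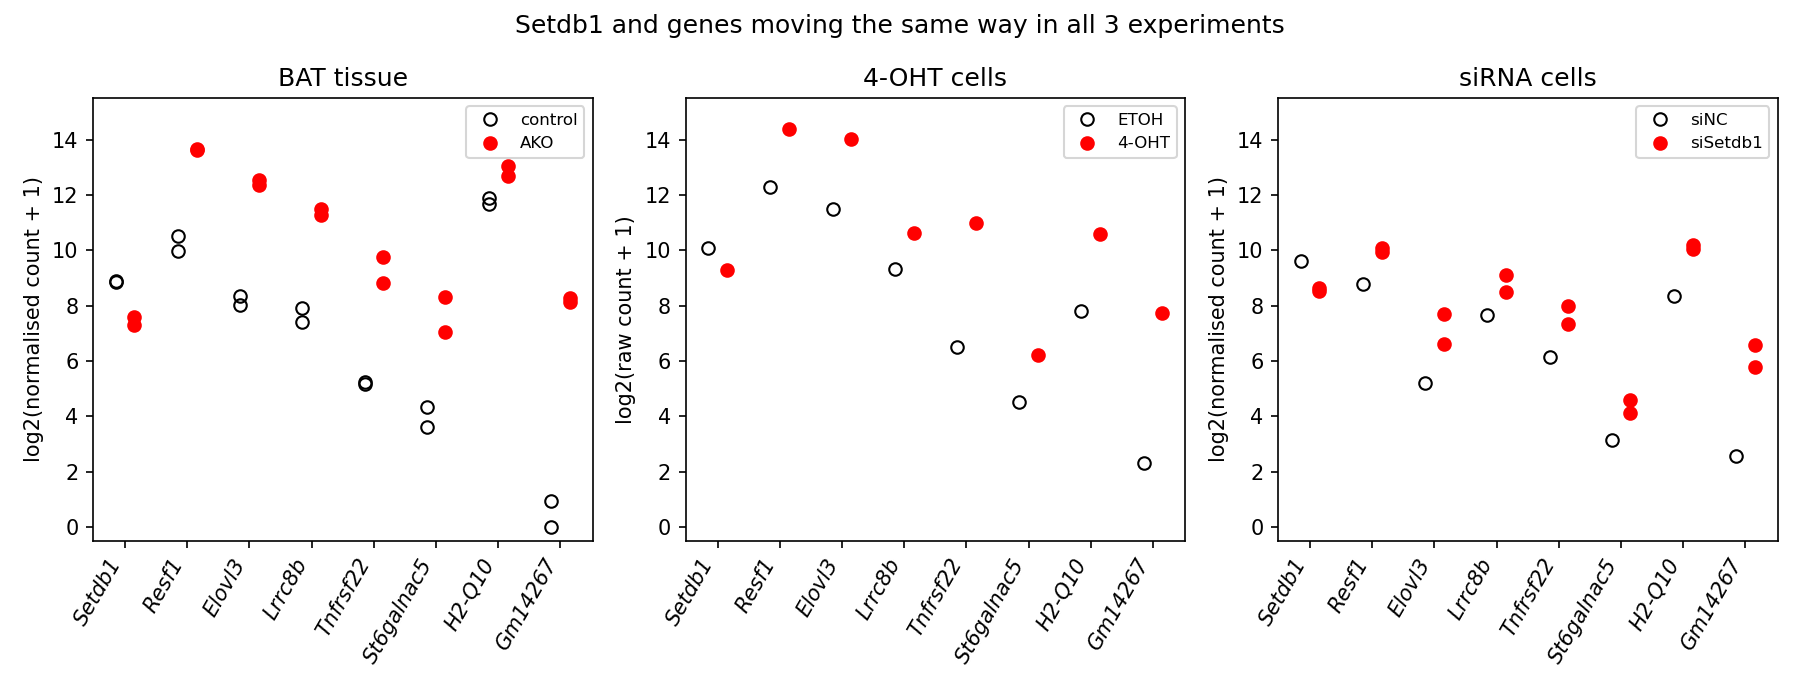
Each point is 1 library, with log2(normalised count + 1) on the vertical axis for BAT and siRNA cells and log2(raw count + 1) for 4-OHT cells; open points are controls and filled points are Setdb1 AKO, 4-OHT or siSetdb1. Setdb1 lies below its control in each experiment, and Resf1, Elovl3, Lrrc8b, Tnfrsf22, St6galnac5, H2-Q10 and Gm14267 lie above theirs.

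Setdb1 AKO was compared with control BAT to find transcripts that differ between these groups in the tissue. Tex19.1, Bglap3 and Mlana, without a read in control BAT, were found in both Setdb1 AKO libraries, and Rpl29 and Nnat were among the genes that fell. Tex19.1 (chromosome 11, 121146143 to 121148319), a germ cell gene, had no read in either control library and 402 ± 32.0 normalised counts in Setdb1 AKO (SD, n = 2), at least 278-fold higher against a floor of 3 reads over the group (limma, adjusted p = 2.28e-04). Sycp3 (chromosome 10, 88459569 to 88473236), a component of the synaptonemal complex of meiosis, rose from 72.4 ± 5.2 to 1481 ± 164 normalised counts (log2 fold change 4.33, SE 0.18; limma, adjusted p = 1.16e-04). Elovl3 (chromosome 19, 46131897 to 46135307), an elongase of very long chain fatty acids known from activated brown fat, rose from 293 ± 48.1 to 5652 ± 497 (log2 fold change 4.27, SE 0.17; limma, adjusted p = 1.05e-04). Rpl29 (chromosome 9, 106429454 to 106431568), a protein of the large ribosomal subunit, fell from 1244 ± 49.8 to 21.1 ± 12.4 (log2 fold change -5.94, SE 0.38; limma, adjusted p = 6.70e-04). Nnat (chromosome 2, 157560078 to 157562522), the imprinted gene of neuronatin, fell from 296 ± 47.7 to 48.5 ± 4.5 (log2 fold change -2.58, SE 0.24; limma, adjusted p = 0.00488).

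Among the other genes that rose most were Bglap3 of the osteocalcin family, with no control read and at least 291-fold higher, and Mlana, a melanocyte gene, with no control read and at least 68.8-fold higher. Cfap53, a cilium gene on chromosome 18, had 3 reads in the controls and 566 in Setdb1 AKO, a ratio of 202 (95% counting interval 68.7 to 981). The fitted log2 fold changes were 6.71 for Ube2ql1, a gene related to ubiquitin-conjugating enzymes, 5.84 for Tcfl5, a transcription factor of the testis, 5.07 for Mlf1 and 4.96 for Tgm5, a transglutaminase. Among genes that fell, the log2 fold changes were -3.58 for Pygo1, a cofactor of Wnt signalling, -2.97 for Grin3b, a subunit of NMDA receptors, -2.75 for Gapdhs, the glyceraldehyde-3-phosphate dehydrogenase of sperm, and -2.55 for Sctr, the secretin receptor. They were -2.49 for Rab11fip4, -2.42 for Tmem56, -2.19 for Vat1l and -2.17 for Mmd2. Resf1, a retroelement silencing factor named by the siRNA and shared rules, rose from 1234 ± 332 to 12830 ± 146 normalised counts. Other abundant transcripts, outside the naming rules, were chosen after their values were seen. Mbd1, a methyl-CpG binding protein, rose from 1730 ± 143 to 16007 ± 393. Gm15287, annotated as an antisense RNA, had 1 read in the controls and 13719 in Setdb1 AKO, a ratio of 14700 (95% counting interval 2630 to 580000), and the nuclear RNA Neat1 fell from 27568 ± 291 to 6486 ± 601. Whether the counting used strand was not stated, so reads of overlapping or antisense genes cannot be told apart. Rpl29 is uncertain for another reason, since 61 annotated genes share over 5% of its 31-mers.

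Of 14466 genes tested, 145 rose and 98 fell in Setdb1 AKO BAT (limma on log2(normalised count + 1), false discovery rate below 0.05), of which 131 and 82 changed at least 2-fold. All 243 had both Setdb1 AKO libraries on the same side of both control libraries, and 2564 genes had an unadjusted p below 0.05. The quasi-likelihood test of edgeR was the planned test and was run here on recovered reads. It called 147 and 102 genes, and 240 genes were called by both tools. The limma test was chosen after the deposited unit was seen. The authors' deposited table had 578 genes with an adjusted p below 0.05, 331 higher and 247 lower. With 2 mice per group the counts depended on single libraries: limma called 22 higher and 2 lower without control 1, 22 and 0 without control 2, 98 and 59 without Setdb1 AKO 1 and 52 and 40 without Setdb1 AKO 2. Of the 10 named higher genes, Ube2ql1, Mlf1, Sycp3 and Elovl3 were tested and called in all 4 of these fits; Tex19.1, Bglap3, Cfap53 and Tcfl5 were called without either control but fell below the filter, and were not tested, without either Setdb1 AKO library. Of the 10 named lower genes, 0 were called in all 4 fits, against 10 with all libraries. Without control 1 the adjusted p (limma) was 0.0881 for Mlana, 0.162 for Tgm5, 0.0608 for Rpl29, 0.105 for Nnat, 0.247 for Grin3b, 0.313 for Sctr, 0.178 for Rab11fip4, 0.178 for Tmem56, 0.263 for Vat1l and 0.0518 for Mmd2, and without control 2 the same 10 were lost. Without Setdb1 AKO 2 it was 0.06 for Pygo1 and 0.0717 for Gapdhs (limma), which were not tested without a control. With no filter on low values limma called 11 and 0 genes.

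The best known genes of brown fat did not pass the test in BAT. Ucp1, the uncoupling protein of heat production, read 97616 ± 13531 normalised counts in control and 83743 ± 29511 in Setdb1 AKO BAT (SD, n = 2; limma, adjusted p = 0.751), and the log2 fold changes were 0.06 for Ppargc1a, -0.03 for Cidea and -0.36 for Prdm16. Dio2, the deiodinase that activates thyroid hormone, read 19158 ± 1096 and 9497 ± 4296 (log2 fold change -1.09; limma, adjusted p = 0.135, and 0.0116 without Setdb1 AKO 1). With DESeq2 it passed at -1.01 (adjusted p = 0.00885), and the range over the alternatives was 0.00885 to 0.551; the fitted change was -1.57 without Setdb1 AKO 1 and -0.61 without Setdb1 AKO 2. The adipocyte genes Adipoq, Pparg and Fasn had log2 fold changes of 0.36, -0.08 and 0.58. Of 30 measured thermogenic genes, 3 rose and none fell, namely Elovl3, Bmp8b (log2 fold change 3.78), a secreted factor of brown fat, and Acot11 (1.62), an acyl-CoA thioesterase; adjusted over the list alone, 5 rose and 2 fell. The list median was 0.16 (limma camera, adjusted p = 0.233, and 0.0211 without Setdb1 AKO 2); the median was -0.02 without Setdb1 AKO 1 and 0.07 without control 1. General adipocyte genes had a median of 0.12 over 25 members with no call, and none adjusted over the list alone (limma camera, adjusted p = 0.244, and 0.00558 without Setdb1 AKO 2); the median was 0.05 without Setdb1 AKO 1, 0.19 without control 1 and 0.21 without Setdb1 AKO 2. Of 39 nuclear genes of oxidative phosphorylation none was called, nor adjusted over the list alone, with a median of 0.05; the median turned to -0.15 without Setdb1 AKO 1 (limma camera, adjusted p = 0.0137) and was 0.26 without Setdb1 AKO 2 (2.34e-07), 0.02 without control 1 and 0.10 without control 2.

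Lists of lipid genes and of mitochondrially encoded genes shifted upward as groups in BAT, mostly through members that did not pass the test singly. Nuclear genes of oxidative phosphorylation did not (limma camera, adjusted p = 0.386). Of 18 genes of de novo lipogenesis 15 were positive, with a median of 0.60 and no call over all genes; 4 rose adjusted over the list alone, and Srebf1, its transcription factor, read 2770 ± 425 and 4715 ± 338 normalised counts (limma, adjusted p = 0.0772). The list test gave an adjusted p of 7.42e-04 (limma camera), and the call was lost with an estimated correlation (limma camera, adjusted p = 0.848 with an estimated correlation). Of 30 mitochondrially encoded genes 28 were positive, with a median of 0.44, no call over all genes and 3 adjusted over the list alone (limma camera, adjusted p = 7.42e-04). This call was lost too (limma camera, adjusted p = 0.848 with an estimated correlation). No list passed in that setting, where the smallest unadjusted p was 0.0685 (limma camera) with few residual degrees of freedom. Such losses cannot tell 1 list from another. Mitochondrial reads were 12.68% and 16.59% of the control libraries and 15.78% and 15.41% of the Setdb1 AKO libraries. The list takes in transfer RNA genes as well as protein genes, so its median is not that of respiratory genes alone. The transfer RNA gene mt-Ti read 7.2 normalised counts in control and 16.5 in Setdb1 AKO BAT, and the protein gene mt-Co2 5331 and 9142. Fatty acid oxidation had a median of 0.23 over 21 genes (limma camera, adjusted p = 0.0225, and 0.848 with an estimated correlation). Its 1 call was Eci2, an enoyl-CoA isomerase, which rose from 1814 ± 134 to 31833 ± 1028 normalised counts (limma, adjusted p = 1.05e-04); adjusted over the list alone 1 gene rose and 1 fell. Cholesterol synthesis and uptake had a median of 0.31 over 21 genes (limma camera, adjusted p = 0.0406, and 0.848 with an estimated correlation), yet its 1 call, the synthase gene Hmgcs1, fell by 1.27 on the log2 scale; adjusted over the list alone 5 rose and 2 fell. With no filter the cholesterol call was lost (limma camera, adjusted p = 0.0555, range over the alternatives 2.32e-04 to 0.848), and with a replicate block that of fatty acid oxidation (0.0507, range 4.52e-07 to 0.848). Markers of fibroblasts and preadipocytes moved the same way, with a median of 0.86. The mitochondrially encoded median was 0.28 without control 1. Without control 1, control 2, Setdb1 AKO 1 and Setdb1 AKO 2 in turn, the medians were 0.92, 0.36, 0.94 and 0.27 for lipogenesis, 0.38, 0.15, 0.66 and 0.05 for cholesterol and 0.24, 0.28, 0.04 and 0.39 for fatty acid oxidation genes. Without control 2 the list adjusted p was 0.0848 for lipogenesis, 0.226 for cholesterol and 0.131 for fatty acid oxidation (limma camera); without Setdb1 AKO 2 it was 0.0828 and 0.527 for the first pair, and for fatty acid oxidation it was 0.0929 without control 1 and 0.320 without Setdb1 AKO 1.

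Germ line, fibroblast, inflammatory, interferon-stimulated and erythroid genes also stood higher as groups in Setdb1 AKO BAT. Of 6 measured germ line genes, Sycp3 and Sycp2 (log2 fold change 2.95), both of the synaptonemal complex, rose, and 4 rose adjusted over the list alone; the median was 2.57 (limma camera, adjusted p = 0.00287, and 0.848 with an estimated correlation). Of 15 fibroblast and preadipocyte markers, Pi16 (2.87) and Pdpn (2.32) rose, and 8 rose adjusted over the list alone, with a median of 0.86 (limma camera, adjusted p = 4.39e-04). Both list calls were lost with an estimated correlation (limma camera, adjusted p = 0.848 with an estimated correlation). Inflammatory and NF-kB genes had a median of 0.65 over 23 genes with no call, and none adjusted over the list alone; it was 0.34 without control 1, 0.72 without control 2, 0.93 without Setdb1 AKO 1 and 0.12 without Setdb1 AKO 2. The chemokine Cxcl2 read 135 ± 73.6 and 341 ± 31.4 (limma camera, adjusted p = 0.00827 for the list, and 0.848 with an estimated correlation). Interferon-stimulated genes had a median of 0.24 over 32 genes with no call, and none adjusted over the list alone (limma camera, adjusted p = 0.0406, and 0.848 with an estimated correlation). Erythroid markers had a median of 0.55 over 6 genes with no call and 1 adjusted over the list alone (limma camera, adjusted p = 0.0294). The inflammatory, interferon and erythroid calls were thus lost (limma camera, adjusted p = 0.848 with an estimated correlation), in a setting in which no list passed. The germ line median was 1.69 without control 2, with too few members measured for a test without either Setdb1 AKO library, and the fibroblast median was 0.52 without Setdb1 AKO 2. The erythroid median was 0.27 without control 1. Without control 1 the adjusted p was 0.231 for inflammatory and 0.322 for erythroid genes, the latter 0.05 without Setdb1 AKO 1 (limma camera). Without control 2 the interferon median was -0.05 (limma camera, adjusted p = 0.785), and without Setdb1 AKO 2 the adjusted p was 0.881 for interferon and 0.431 for inflammatory genes (limma camera). The interferon median was 0.04 without Setdb1 AKO 2, 0.54 without control 1 and 0.68 without Setdb1 AKO 1. The interferon call was lost with a filter of at least 50 in 2 libraries (limma camera, adjusted p = 0.0824) and with no filter (0.0635), with a range over the alternatives of 5.70e-05 to 0.881. The erythroid call was lost with no filter (limma camera, adjusted p = 0.0883, range 0.00555 to 0.848).

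Markers of other cell types did not pass the list test in BAT, although single members rose. Macrophage markers had a median of 0.03 over 19 genes with 1 call, Cd14, which rose by a log2 fold change of 0.96; the median was 0.43 without control 1 and -0.31 without control 2 (limma camera, adjusted p = 0.00132 and 0.0440). Lymphocyte markers had a median of -0.45 over 10 genes, of which 9 were negative and 1, Ighm, the constant region of immunoglobulin M, rose from 51.4 ± 6.6 to 7235 ± 2618 normalised counts (limma, adjusted p = 1.05e-04); the median turned to 0.22 without control 1 and was -0.11 without Setdb1 AKO 2 and -1.16 without control 2 (limma camera, adjusted p = 0.0167). The medians were 0.01 for endothelial, 0.18 for mural, 0.25 for neutrophil and mast cell, -0.35 for skeletal muscle and 0.28 for Schwann cell and neuron markers, with no call in any. They were -1.42 for muscle without control 1 (limma camera, adjusted p = 0.00183), and 0.37 for mural (0.00991) and 0.67 for Schwann cell and neuron markers (0.0179) without Setdb1 AKO 2. The directions were not stable, except that the median of endothelial markers stayed positive. Without control 1, control 2, Setdb1 AKO 1 and Setdb1 AKO 2 in turn, the medians were -1.42, 0.51, -0.38 and -0.14 for muscle and -0.19, 0.56, -0.10 and 0.67 for Schwann cell and neuron markers. They were 0.01, 0.51, 0.77 and -0.07 for neutrophil and mast cell, and 0.22, 0.10, -0.02 and 0.37 for mural markers. Those of endothelial markers were 0.02, 0.03, 0.04 and 0.15, and those of macrophage markers 0.43, -0.31, 0.16 and -0.12. Adjusted over the list alone, the macrophage and lymphocyte lists had 1 higher and 0 lower each. White adipocyte and lymph node genes, 4 of them measured, were too few to test and had a median of 0.68.

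The remaining lists did not pass the list test in BAT either, with single members called. Of 28 matrix genes Ctgf, a secreted matrix protein, rose by 1.46 with a list median of 0.16 (limma camera, adjusted p = 0.0587, 0.0283 without control 1 and 1.79e-05 without Setdb1 AKO 1), and of 22 proliferation genes Plk1, a mitotic kinase, rose by 2.63 with a list median of 0.19. Of 27 imprinted genes Nap1l5 rose by 1.77 and Nnat fell (list median -0.21). Of 328 Zfp genes, which encode zinc finger proteins, 10 rose and 7 fell, 20 and 25 adjusted over the list alone, and Zfp445 rose from 625 ± 103 to 2158 ± 92.2 normalised counts (list median -0.13, against a mean of 0.03; limma camera, adjusted p = 0.149, and 0.0155 without Setdb1 AKO 2). Clustered protocadherins had a median of -0.42 over 21 genes, p53 targets 0.07 over 23, stress response genes 0.11 over 28, of which Psph of serine synthesis rose by 1.09, and nucleic acid sensing genes 0.08 over 20. Of 19 H3K9 methylation genes Resf1 rose and Setdb1 fell, 2 and 2 adjusted over the list alone, while Atf7ip, a binding partner of SETDB1, read 215 ± 18.7 and 473 ± 94.9 (limma, adjusted p = 0.0503) and Trim28, a corepressor, 1584 ± 193 and 1071 ± 56.6 (limma, adjusted p = 0.134). Adjusted over the list alone, imprinted genes had 2 higher and 2 lower, protocadherins 1 and 1, stress response genes 3 and 0, and p53, proliferation and matrix lists 1 and 0 each. With a filter of at least 50 in 2 libraries limma camera called the proliferation (adjusted p = 0.025, range over the alternatives 0.025 to 0.848), matrix (0.0474, range 1.79e-05 to 0.940) and Zfp lists (0.00447, range 0.00447 to 0.848), the last at a median of -0.26. Without control 1, control 2, Setdb1 AKO 1 and Setdb1 AKO 2 in turn, the medians were 0.14, 0.18, -0.05 and -0.30 for protocadherins and -0.01, 0.23, 0.20 and -0.08 for p53 targets. They were -0.07, 0.10, 0.33 and -0.16 for stress response and 0.23, 0.00, 0.17 and -0.05 for nucleic acid sensing genes. They were 0.26, 0.05, 0.36 and -0.09 for matrix, 0.12, 0.16, 0.08 and 0.18 for proliferation, -0.13, -0.31, -0.29 and -0.13 for imprinted and -0.13, -0.18, -0.19 and -0.20 for Zfp genes.

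**Figure D2:**
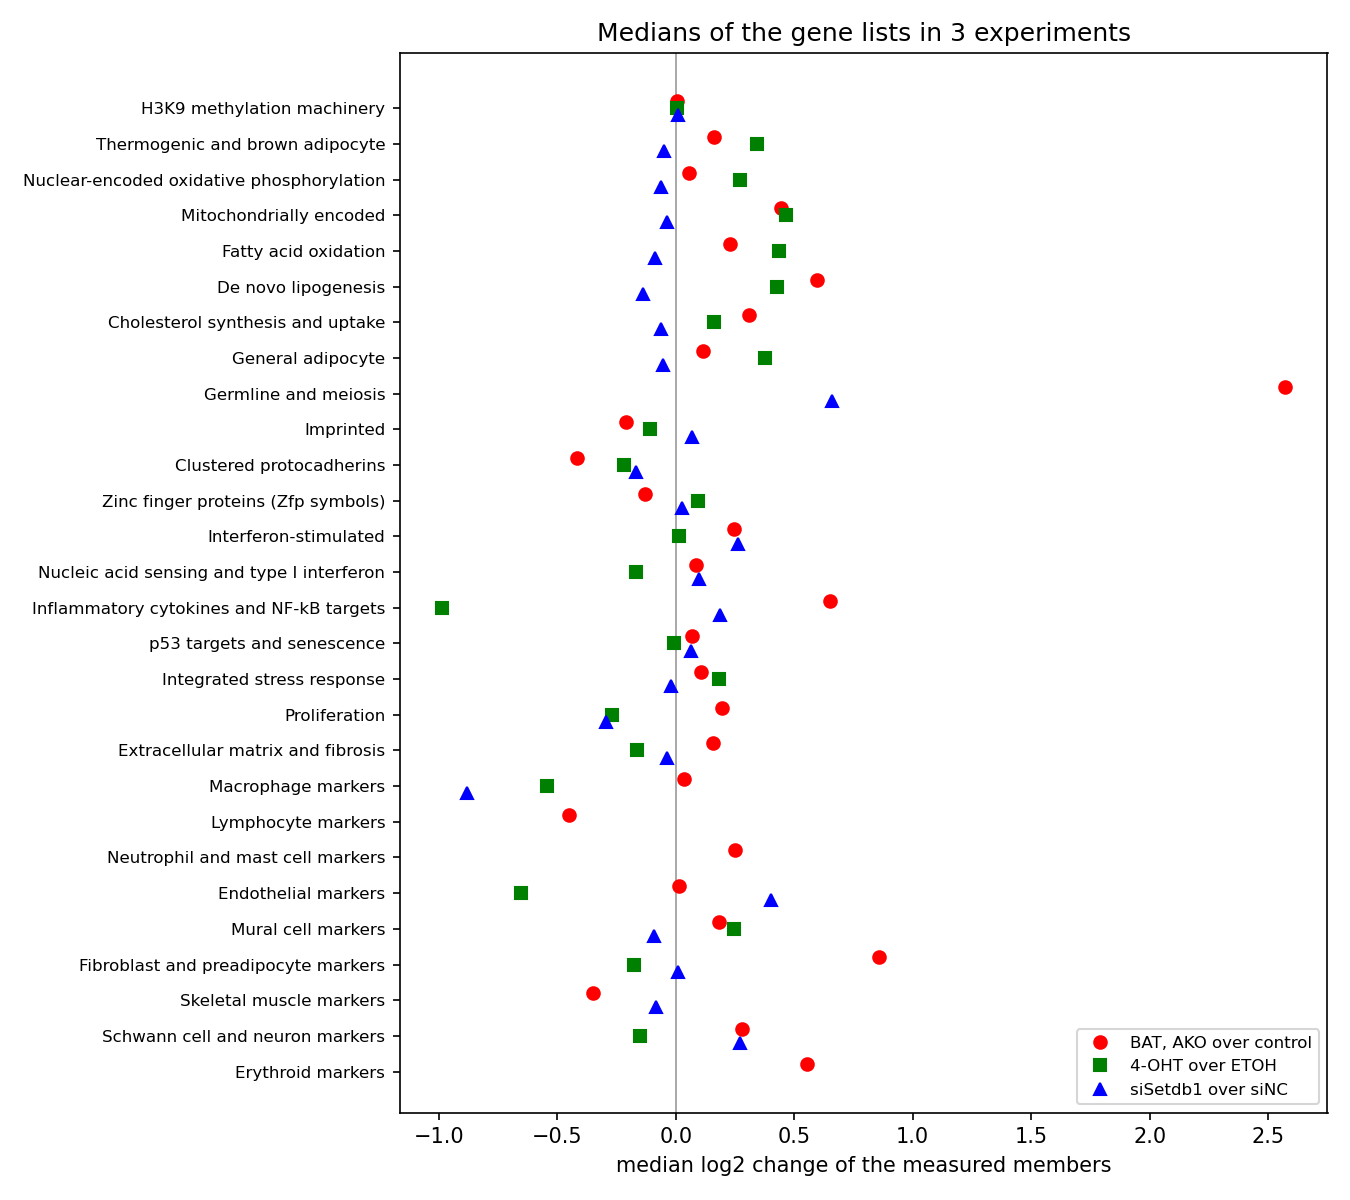
Each row is 1 gene list, with the median log2 change of its measured members on the horizontal axis; circles show BAT, squares 4-OHT and triangles siRNA. De novo lipogenesis reads 0.60 in BAT, 0.43 in 4-OHT and -0.14 in siRNA, and inflammatory genes read 0.65, -0.99 and 0.19. Without Setdb1 AKO 2 these BAT medians were 0.27 and 0.12.

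Knockdown of Setdb1 in primary brown adipocytes was used to find transcripts that differ in cultured cells. Few genes passed the test, and those that did included partners of SETDB1. Atf7ip (chromosome 6, 136506167 to 136610862) rose from 790.4 normalised counts in siNC to 1777.5 and 1795.3 in the siSetdb1 libraries (log2 fold change 1.18, SE 0.12; limma, adjusted p = 0.00483). Resf1 (chromosome 6, 149309414 to 149335663) rose from 443.1 to 978.9 and 1087.6 (1.22, SE 0.14; limma, adjusted p = 0.0106). H2-Q10 (chromosome 17, 35470089 to 35474563), a class I histocompatibility gene with close relatives, rose from 327.6 to 1044.8 and 1172.1 (1.75, SE 0.14; limma, adjusted p = 9.23e-04). Acp5, an acid phosphatase, rose from 926.6 to 1614.3 and 1738.3 (limma, adjusted p = 0.0468), and Rdh12, a retinol dehydrogenase, fell from 374.0 to 138.8 and 121.2 (log2 fold change -1.52; limma, adjusted p = 0.0468). Gm14267, a transcribed pseudogene named by the rule for genes shared by all experiments, rose from 4.9 to 53.7 and 93.7 (limma, adjusted p = 0.0468).

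Other genes of the siRNA experiment moved the same way in both siSetdb1 libraries without passing the limma test; edgeR called 8 of them, namely Entpd4b, Elovl3, Megf10, Tnfrsf22, Sumo2, Lyz2, Sept6 and Aldh1b1. Above siNC were Entpd4b (19.7 in siNC, 74.0 and 287.2), Bcas1 (17.8, 53.7 and 75.4), Elovl3 (35.5, 97.3 and 207.7), Megf10 (61.2, 158.1 and 192.5), Tnfrsf22 (69.1, 161.1 and 253.6) and Tslp (52.3, 118.6 and 124.2), in normalised counts of siNC and of libraries 1 and 2. Below siNC were Sumo2 (666.1 in siNC, 247.3 and 106.9), Lyz2 (526.9, 244.2 and 166.0), the lysozyme of macrophages, Gdf10 (112.5, 44.6 and 45.8), Aldh1b1 (202.3, 94.2 and 90.6), Gnb1l (62.2, 30.4 and 29.5), Insl3 (78.9, 39.5 and 35.6), Sept6 (353.3, 179.4 and 168.0) and Lum (106.6, 54.7 and 44.8), the matrix protein lumican. Entpd4b and Sumo2 have near copies in the genome, and how the counting split their reads was not stated. The libraries differed in size of change: the log2 ratios of libraries 1 and 2 to siNC were 1.85 and 3.80 for Entpd4b, 1.43 and 2.51 for Elovl3, 1.21 and 1.86 for Tnfrsf22, -1.43 and -2.63 for Sumo2 and -1.11 and -1.66 for Lyz2. The log2 fold changes were -0.15 for Ucp1, 0.26 for Dio2 and -0.36 for Fasn, and -0.07 for Cidea, whose ratios were -0.25 in library 1 and 0.11 in library 2. Of 15224 genes tested, 5 rose and 1 fell (limma, false discovery rate below 0.05), and 770 had an unadjusted p below 0.05. The test has 1 residual degree of freedom and assumes that the lone siNC library varies like the siSetdb1 libraries. The counts moved with the settings. The planned edgeR test, run on recovered reads, called 34 and 8, including all 6 genes called by limma. With limma the counts were 12 and 5 after RLE scaling, 14 and 5 after TMM scaling, and 0 and 0 with no filter.

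Interferon-stimulated genes stood higher and macrophage markers lower after knockdown, as groups. Of 32 interferon-stimulated genes 31 were positive, with a median of 0.26 and no call by limma over all genes or adjusted over the list alone (limma camera, adjusted p = 5.24e-11). This call and the other 7 here were lost with an estimated correlation (limma camera, adjusted p = 0.735 with an estimated correlation for each). No list passed in that setting, where the smallest unadjusted p was 0.154 (limma camera) with 1 residual degree of freedom. The losses therefore say little of these lists. Zbp1, a sensor of nucleic acids and the 1 member called by edgeR (adjusted p = 0.0118), read 542.7 normalised counts in siNC and 1099.5 and 760.7 in siSetdb1. Inflammatory genes had a median of 0.19 over 20 genes (limma camera, adjusted p = 0.0339), germ line genes 0.66 over 5 (0.0245) and Schwann cell and neuron markers 0.27 over 7 (0.0232). Macrophage markers had a median of -0.88 over 15 genes, of which 12 were negative (limma camera, adjusted p = 0.00108); C1qa, of the complement system, read 59.2, 26.3 and 32.6 normalised counts, whereas Mpeg1, also of macrophages and called higher by edgeR, read 318.7, 595.9 and 489.8. Proliferation genes had a median of -0.29 over 28 genes (limma camera, adjusted p = 1.08e-06), de novo lipogenesis -0.14 over 18 (0.00108) and nuclear genes of oxidative phosphorylation -0.06 over 39 (0.0232). With at least 50 in 1 library the inflammatory and macrophage calls were lost (limma camera, adjusted p = 0.0724, range over the alternatives 0.0313 to 0.754, and 0.0737, range 8.28e-04 to 0.735). The macrophage median was then -0.57. With no filter the germ line and Schwann cell and neuron calls were lost (limma camera, adjusted p = 0.259, range 0.0218 to 0.833, and 0.349, range 0.0218 to 0.754). With library 1 alone the median was 0.31 for inflammatory, -0.24 for lipogenesis, 0.38 for germ line, 0.13 for Schwann cell and neuron and -0.09 for proliferation genes. With library 2 alone it was 0.13 for interferon-stimulated, -0.58 for macrophage, 1.01 for germ line, 0.51 for Schwann cell and neuron, -0.48 for proliferation and -0.06 for lipogenesis genes, and oxidative phosphorylation read -0.02 in library 1 and -0.10 in library 2. Adjusted over the list alone, 1 inflammatory gene rose, 1 macrophage gene rose and 1 fell, and no gene of the other 6 lists was called.

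The other lists did not pass the list test after knockdown. Among H3K9 methylation genes Atf7ip and Resf1 rose, with a median of 0.01 over 20 genes, and adjusted over the list alone Setdb1 fell as well. The medians were -0.05 for thermogenic, -0.04 for mitochondrially encoded, -0.09 for fatty acid oxidation, -0.06 for cholesterol and -0.05 for general adipocyte genes. They were 0.07 for imprinted genes, -0.17 for clustered protocadherins, 0.02 for Zfp genes, 0.10 for nucleic acid sensing, 0.06 for p53 targets, -0.02 for stress response and -0.04 for matrix genes, whose mean was 0.02. Among other cell types they were 0.40 for endothelial, -0.09 for mural, 0.01 for fibroblast and preadipocyte and -0.08 for skeletal muscle markers. With libraries 1 and 2 taken singly, the endothelial medians were 0.04 and 0.21, the skeletal muscle medians -0.28 and 0.09, the mural medians -0.19 and -0.0021 and the fibroblast medians 0.02 and -0.06. Other medians that turned or moved were 0.02 and -0.13 for mitochondrially encoded, -0.13 and 0.03 for cholesterol, -0.10 and -0.0079 for thermogenic and -0.09 and -0.02 for general adipocyte genes. They were -0.12 and 0.01 for stress response, 0.14 and 0.02 for p53 targets, 0.04 and 0.12 for nucleic acid sensing, 0.10 and 0.04 for imprinted and -0.0090 and 0.02 for matrix genes. Those of Zfp genes were 0.02 and 0.04, and those of H3K9 methylation genes 0.0025 and 0.0091. Adjusted over the list alone, 3 matrix genes rose, 1 fibroblast gene rose and 1 fell, and 1 gene rose in each of the thermogenic, mitochondrially encoded, nucleic acid sensing, p53 and lymphocyte lists. Lymphocyte, neutrophil and mast cell, white adipocyte and lymph node genes had fewer than 5 measured members, with medians of 0.54, 0.27 and -0.03, and no erythroid marker was measured. Across 15224 genes the log2 ratios of the 2 siSetdb1 libraries to their shared siNC had a Pearson correlation of 0.504, against 0.501 simulated for unchanged libraries that share a control. The covariance was 0.124, against 0.0602 simulated, but 0.0529 against 0.0323 with a prior count of 10 and 0.0262 against 0.0229 among 9086 genes with at least 200 counts in 1 library, where the correlation was 0.557 against 0.503. Genes are not independent replicates.

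Induced deletion in primary brown adipocytes was compared in 1 library of 4-OHT and 1 of ETOH. No test was made, and the values describe those libraries. There was no library of cells without the inducible Cre given 4-OHT. Effects of 4-OHT or of Cre activity therefore cannot be told apart from deletion of Setdb1. Among protein-coding genes, members of a gene cluster of tumour necrosis factor receptors on chromosome 7 were among the largest increases. Tnfrsf22 (143634806 to 143649661) read 90 counts in ETOH and 2029 in 4-OHT, a log2 ratio of 4.52, Tnfrsf23 read 267 and 2016 (2.96), and Tnfrsf26 78 and 467 (2.60); these are related genes. Atf7ip2, a relative of Atf7ip, read 8 and 122 counts, Cyp2b10, a cytochrome P450, 19 and 203, Serpina10 4 and 50, Itpka, a kinase of inositol phosphate, 210 and 1772, Fam57b 130 and 1002, H2-Q10 223 and 1525, and Pitx3, a homeobox gene beside Elovl3, 68 and 466. The largest decreases among them were Entpd4b (427 and 23 counts), Vtn (50 and 6), the plasma protein vitronectin, Scg2 (93 and 13), Il33 (63 and 10), Il1b (95 and 18), mt-Atp6 (472 and 97), Camk2a (54 and 10), Rab6b (138 and 28), Vsig4 (235 and 51), a receptor of macrophages, and Cxcl12 (3096 and 703), a chemokine. Outside protein-coding genes, Gm14267, named by the rule for shared genes, read 4 counts in ETOH and 213 in 4-OHT. Others were chosen after their values were seen. The antisense RNA Gm15287 read 0 and 1729 counts, 9130204K15Rik, a long noncoding RNA, 2 and 158, and the pseudogene Gm13284 1 and 79. Ighm read 67 and 1311, and Gt(ROSA)26Sor 6 and 129. Among brown fat genes Ucp1 read 8133 and 8735 counts (log2 ratio 0.16), Cidea 3602 and 6118 (0.82), Elovl3 2872 and 16633 (2.59), Fasn 161916 and 225707 (0.53) and Dio2 243 and 217. Of 13969 genes with at least 50 counts in either library, 179 were at least 2-fold higher and 231 at least 2-fold lower in 4-OHT. The authors' deposited table had 59 genes with an adjusted p below 0.05, 37 higher and 22 lower, from the same 1 library per group. With a minimum of 200 counts, 83 genes were at least 2-fold higher and 95 lower.

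Genes of adipocyte metabolism stood above ETOH in the 4-OHT library and inflammatory and macrophage genes below it. The median log2 ratio was 0.34 for thermogenic genes, 0.27 for nuclear genes of oxidative phosphorylation (38 of 39 positive), 0.47 for mitochondrially encoded genes, 0.44 for fatty acid oxidation, 0.43 for de novo lipogenesis and 0.38 for general adipocyte genes. Each of the 6 medians was at percentile 100 of 10000 random lists matched on size and expression. Lists whose members move together reach extreme percentiles easily against such random genes. The same libraries also differed in sex-linked transcripts. Xist, the RNA of X inactivation, read 10697 counts in ETOH and 5777 in 4-OHT. The Y-linked genes Ddx3y read 2098 and 2674, Eif2s3y 1542 and 2179, Uty 892 and 1169 and Kdm5d 517 and 610. The cultures may therefore differ in their mixture of cells, which cannot be told apart from deletion as a source of the list shifts. Fabp4, the fatty acid binding protein of adipocytes, read 143314 counts in ETOH and 175925 in 4-OHT, Scd1, a desaturase, 707319 and 915606, and mt-Co1 368031 and 517678. Macrophage markers had a median of -0.54 (percentile 0), with 17 of 18 below ETOH, and Lyz2 read 80947 and 43473 counts. Inflammatory genes had a median of -0.99 (percentile 0), with 11 of 23 at least 2-fold lower, and the chemokine Ccl2 read 8062 and 3399 counts. Matrix genes had a median of -0.16 (percentile 0.01), proliferation genes -0.27 (0.01), fibroblast and preadipocyte markers -0.18 (1.09) and endothelial markers -0.65 (0.19). Cholesterol genes had a median of 0.16 (percentile 99.35), stress response genes 0.18 (99.93), Zfp genes 0.09 (100) and mural markers 0.25 (98.72). Imprinted genes had a median of -0.11 (percentile 1.27), clustered protocadherins -0.22 (1.59), nucleic acid sensing genes -0.17 (0.65), Schwann cell and neuron markers -0.15 (9.97), p53 targets -0.01 (27.09), H3K9 methylation genes 0.01 (39.74) and interferon-stimulated genes 0.01 (58.71). Germ line, lymphocyte, neutrophil and mast cell, skeletal muscle, erythroid, and white adipocyte and lymph node genes had fewer than 5 measured members, with medians of 1.30, 1.88, -0.72, -0.23, 0.07 and 0.60; the germ line gene Sycp3 read 37 and 178 counts.

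A small set of genes moved the same way in all 3 experiments. Of 105 genes called higher in BAT and measured in each experiment, 7 were at least 1.5-fold higher in 4-OHT and in both siSetdb1 libraries: Elovl3, Lrrc8b, a subunit of volume-regulated anion channels, Resf1, Gm14267, Tnfrsf22, St6galnac5, a sialyltransferase, and H2-Q10. Of 83 called lower, 1 was at least 1.5-fold lower in each, the targeted gene Setdb1. Resf1 had a log2 change of 3.40 in BAT, 2.16 in 4-OHT and 1.22 in siRNA, Elovl3 of 4.27, 2.59 and 1.97, Tnfrsf22 of 4.08, 4.52 and 1.54, and Lrrc8b of 3.71, 1.33 and 1.13. Genes called higher in BAT had a median log2 ratio of 0.28 in 4-OHT, with 77 of 110 positive, and of 0.13 in siRNA, with 74 of 119 positive, both at percentile 100 of 10000 matched random lists. With DESeq2 calls the medians were 0.23 in 4-OHT (percentile 100, 198 of 290 positive) and 0.03 in siRNA (percentile 99.6, 168 of 304 positive). With library 1 alone the siRNA median of the limma calls was 0.09 (percentile 99.96). Genes called lower had medians of -0.03 in 4-OHT (percentile 8.11, 48 of 83 negative) and -0.04 in siRNA (percentile 7.15, 55 of 96 negative). The percentiles in 4-OHT and siRNA were 0.84 and 1.62 with DESeq2 calls and 11.7 and 2.37 when limited to 2-fold calls. With siSetdb1 library 1 alone the siRNA percentile was 20.18, and with library 2 alone 8.67. Among 13409 genes tested in both BAT and siRNA, 7 were called higher in BAT by limma and in siRNA by edgeR, against 0.266 for independent lists: Ctgf, Elovl3, Gm14267, H2-Q10, Lrrc8b, Resf1 and Tnfrsf22. Only Setdb1 was called lower in both, against 0.043 for independent lists. It is the targeted gene, so its fall was fixed by the design and says nothing of overlap among other genes. The BAT calls of H2-Q10, Tnfrsf22 and St6galnac5 were lost without control 1 (limma, adjusted p = 0.277, 0.0827 and 0.149) and without control 2 (0.378, 0.0705 and 0.207), and those of H2-Q10 and St6galnac5 also without Setdb1 AKO 2 (0.0743 and 0.0744).

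**Figure D3:**
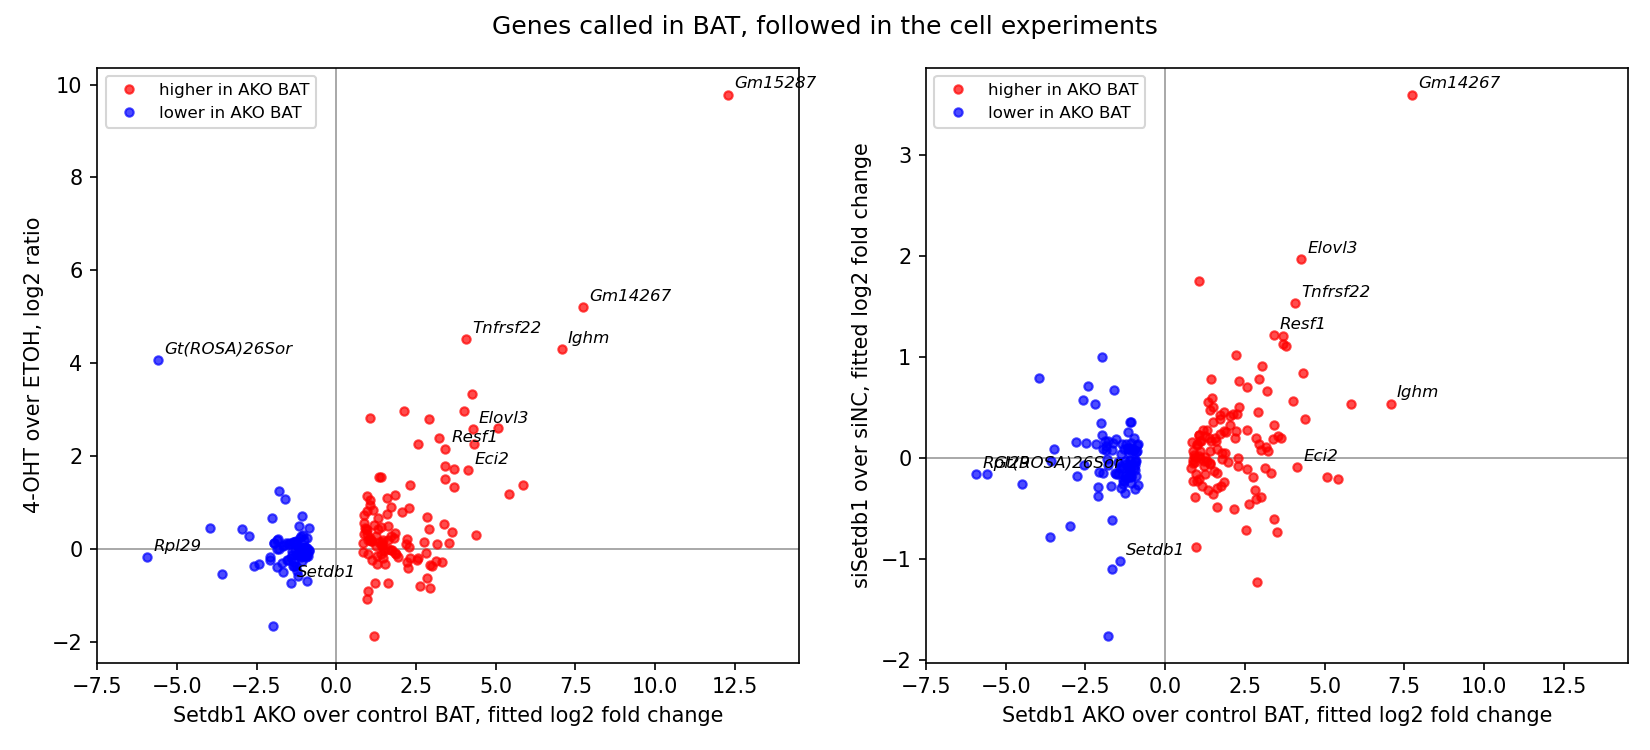
Each point is 1 gene called in BAT, with its fitted log2 fold change in BAT on the horizontal axis and its log2 ratio in 4-OHT (left) or fitted log2 fold change in siRNA (right) on the vertical axis; red points were called higher and blue points lower in Setdb1 AKO BAT. Resf1 reads 3.40 against 2.16 and 1.22, and Rpl29 reads -5.94 against -0.18 and -0.16.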

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

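All of the tests in this part were chosen after the results were seen, except the test of reads on copies of Rpl29.

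The change on Setdb1 loss differed between BAT and siRNA cells for 28 of the 40 named genes measured in both. This used a limma test of the difference over all libraries, with the false discovery rate taken over the 40. Signs were opposite in 12 of the 28, but none of the 12 was called by limma in both experiments. Some had 1 side near 0, such as Mlf1 in siRNA (-0.19, SE 0.32) and Sumo2 (0.02, SE 0.24) and Sept6 (0.03, SE 0.29) in BAT. An opposite sign there does not show an opposite response. Named genes below the filter in siRNA cells, such as Tex19.1 and Bglap3, were not compared. The genes had been named for a large change, which favours such differences, and BAT and cells differ in the way Setdb1 was removed and in cell mixture. The BAT minus siRNA difference in log2 fold change was 5.31 for Tcfl5, 5.26 for Mlf1, 4.14 for Gm14267, 3.49 for Sycp3, 2.58 for Lrrc8b, 2.55 for Tnfrsf22, 2.49 for St6galnac5, 2.30 for Elovl3 and 2.19 for Resf1. It was 2.05 for Sumo2, 1.46 for Gnb1l, 1.32 for Lyz2, 1.31 for Lum and 1.05 for Sept6. It was -5.78 for Rpl29, -3.55 for Pygo1, -3.15 for Nnat, -3.13 for Tmem56, -2.87 for Entpd4b, -2.72 for Vat1l, -2.63 for Rab11fip4, -2.57 for Gapdhs, -2.49 for Sctr, -2.30 for Mmd2, -2.30 for Grin3b, -1.35 for Dio2, -0.68 for H2-Q10 and -0.53 for Trim28. Gt(ROSA)26Sor moved in opposite directions in BAT, where it fell, and in 4-OHT cells, with a log2 ratio of 4.08; that difference was not tested.

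Rpl29 and Gt(ROSA)26Sor were nearly absent in Setdb1 AKO BAT, at 12 and 29 reads against 1318 and 1261 in control BAT for Rpl29, and 14 and 5 reads against 705 and 330 for Gt(ROSA)26Sor. No such loss was seen in the cells, where the median of the log2 ratios of both genes in 4-OHT and both siSetdb1 libraries was -0.12. That cannot decide whether the loss follows Setdb1, since Setdb1 reads remained in the cells (620 in 4-OHT against 1070 in ETOH). Genes called lower in BAT also moved little there as a group, with medians of -0.03 in 4-OHT and -0.04 in siRNA. Reads counted on copies of Rpl29 stay open, since the copies gained 13.61% of the normalised counts that Rpl29 lost. A stretch of another genome carried by the Setdb1 AKO mice may also lower both, and it stays open: 3 genes called lower lay within 5 Mb of either gene, against a median of 1 and a 95th percentile of 5 for random pairs of genes called lower. The Rosa26 locus carries the inducible Cre in the 4-OHT cells, which limits what its reads there mean.

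Ighm was 134-fold higher in Setdb1 AKO BAT. Expression in brown adipocytes that lack Setdb1 is a candidate explanation, with a log2 ratio of 4.30 in 4-OHT and 853 reads in siNC against 1374 and 1056 in siSetdb1, although the siRNA change did not pass the test (log2 fold change 0.54; limma, adjusted p = 0.723, and 0.08 with edgeR). The 4-OHT ratio cannot separate deletion from 4-OHT itself or from a difference between the cultures. Reads that overlap Ighm on the other strand could not be told from it with these data, so the hypothesis is about the locus and not the protein. RNA from other cell types stays open as a source in the tissue, where the lymphocyte list as a whole had a median of -0.45 that turned to 0.22 without control 1 and was -1.16 without control 2.

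Macrophage markers had a negative median in 4-OHT and siSetdb1 cells. The siSetdb1 list call, like every other, was lost with an estimated correlation (limma camera, adjusted p = 0.735 with an estimated correlation) and by fry. Fewer macrophages stays open in both: 17 of 18 markers below ETOH and 12 of 15 negative in siSetdb1 only restate the pattern, and Mpeg1 had a log2 fold change of 0.76 in siSetdb1. Loss of macrophage RNA alone would raise all other lists alike, and TMM scaling takes out such a common rise, so the rise itself could not be seen. It would not set lists apart, yet matrix genes had a median of -0.16 in 4-OHT and general adipocyte genes 0.38. These values argue against it as the source of that difference only, and do not bear on the number of macrophages. Expression within macrophages was not tested.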

How the results depend on the processing

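Chosen after the data were seen were limma as the main test and recovered reads as the input of edgeR, whose test was planned. So were TMM scaling, pseudocounts of 0.5 and 5, the robust variance prior and, for some results, limma-voom and the filter at 50.

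In BAT the calls, 145 higher and 98 lower by limma, were 363 and 286 with DESeq2, 11 and 0 with no filter, 377 and 371 with all libraries in 1 model and 334 and 296 at a false discovery rate below 0.1. Without 1 library they ranged from 22 to 98 higher and from 0 to 59 lower: 22 and 2 without control 1, 22 and 0 without control 2, 98 and 59 without Setdb1 AKO 1 and 52 and 40 without Setdb1 AKO 2. The lone library is assumed to vary like the others, and fewer libraries widen the error. The zero counts stand beside 2564 genes at an unadjusted p below 0.05 and 102 lower by edgeR with all libraries. With the replicate number as a block, which pairs libraries that share only a number, they were 181 and 118 (edgeR 175 and 116) and 9 lists were called. Setdb1 read -1.42 with no filter (limma, adjusted p = 0.206) and -1.56 to -1.28 without 1 library, with an adjusted p from 1.62e-05 to 0.230 over all alternatives. Of 9 lists called, 0 were with an estimated correlation and 0 by limma fry, while its mixed test, which ignores direction, passed 9 of 28 lists in BAT and 0 in siRNA. The smallest unadjusted p with an estimated correlation was 0.0685 (limma camera), so hardly any list could pass in that setting.

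With at least 50 in 2 libraries, limma camera lost the interferon list (adjusted p = 0.0824) and called the proliferation (0.025), matrix (0.0474) and Zfp (0.00447) lists in BAT. Over the fits without 1 library the interferon median ranged from -0.0487 (without control 2) to 0.68, macrophage markers from -0.31 (without control 2) to 0.43 and oxidative phosphorylation from -0.15 (without Setdb1 AKO 1) to 0.26. The cause was not tested.

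In siRNA the limma calls, 5 higher and 1 lower, were 8 and 3 with DESeq2, 37 and 14 with limma-voom, 12 and 5 with RLE, 14 and 5 with TMM, 22 and 7 with at least 50 in 1 library, 34 and 8 with edgeR, 59 and 14 with a robust prior, 10 and 3 at a false discovery rate below 0.1, 2 lower with a pseudocount of 5, and 0 and 0 with no filter and with all libraries in 1 model, beside 770 genes at an unadjusted p below 0.05 in the limma test. Setdb1 passed in limma, DESeq2 and edgeR alternatives at -1.02 with DESeq2 (adjusted p = 0.0278), RLE (0.0103), TMM (0.00873), at least 50 (0.00123), a pseudocount of 5 (0.0491) and a robust prior (4.68e-07), and at -1.03 with limma-voom (1.28e-05) and edgeR (5.51e-05); the range over all alternatives was 4.68e-07 to 1. Of 8 lists called by limma camera, 5 were with at least 50 in 1 library, 0 with an estimated correlation and 0 by fry. With an estimated correlation the smallest unadjusted p of any list was 0.154 (limma camera). Leaving out 1 siSetdb1 library leaves 1 against 1, so it gives ratios and no count. The cause was not tested.

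In 4-OHT the sizes, 179 higher and 231 lower, were 587 and 795 with a minimum of 10 counts, 83 and 95 with 200, and 588 and 855 at 1.5-fold, which follows from the rule. Genes higher in BAT had medians of 0.23 in 4-OHT (percentile 100) and 0.0321 in siRNA (99.6) with DESeq2 calls. Genes lower in BAT had a siRNA median of -0.0585 (percentile 2.37) when limited to 2-fold calls and -0.0332 (1.62) with DESeq2 calls, and a 4-OHT median of -0.0304 (0.84) with DESeq2 calls.

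Of the other values, named genes kept their side of the threshold in 506 values in BAT, 11 of them with the other sign, lost it in 68 and gained it in 2. In siRNA these were 330 (2 with the other sign), 13 and 45, with 14 ratios moved. In 4-OHT 79 stayed within counting error and 23 moved. List values kept theirs in 332 in BAT, 19 of them with the other sign, with 35 lost, 15 gained and 3 called with the other sign. They kept it in 238 in siRNA, 5 with the other sign, with 20 lost and 14 moved, and 69 were unchanged in 4-OHT, 2 with the other sign.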

Other observations

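All of the tests in this part were chosen after the results were seen.

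Genes called higher in Setdb1 AKO BAT lay near one another. Of 145, 25 had another within 100 kb, against a median of 6, an upper limit of the central random range of 14 and a maximum of 22 over 1000 random lists matched on expression. Loss of Setdb1 may raise genes that share a stretch of chromatin, such as Mbd1 and Cfap53, Elovl3 and Pitx3, and Tnfrsf22 and Tnfrsf23. Chromatin as the source was not tested. The random lists were not matched on gene density. Tnfrsf22 and Tnfrsf23 are related genes, and reads shared between copies of families other than Zfp and Gm symbols were not tested. Reads counted on overlapping genes are argued against as the whole source, since 17 remained without overlapping pairs (upper limit 13, maximum 18), and so are zinc finger copies, since 19 of 120 remained without Zfp and Gm symbols (upper limit 10, maximum 20). Genes called lower also lay near one another, 13 of 98 (upper limit 8, maximum 18), so nearness is not confined to genes that rose, and reads running from 1 gene into the next were not tested.

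Srp54b and mt-Co3 varied between libraries of 1 group. Srp54b had 331 and 377 reads in control BAT, 22 and 502 in Setdb1 AKO BAT, 847 in siNC and 1266 and 185 in siSetdb1. The mitochondrial gene mt-Co3 had 3118 and 9630 reads in control and 17810 and 5502 in Setdb1 AKO BAT. Between groups, Entpd4b had 427 reads in ETOH and 23 in 4-OHT, but 20 in siNC and 73 and 282 in siSetdb1. The imprinted RNA H19 had 10533 reads in ETOH and 4698 in 4-OHT.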
